A study of Homo sapiens with 27 samples.

How the data were processed

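RNA was sequenced from Panc1 cells, an established human pancreatic ductal adenocarcinoma line, and from a pair of knockout clones of ARNT made with CRISPR-Cas9. ARNT (aryl hydrocarbon receptor nuclear translocator, also called HIF1B) is the common partner subunit of the hypoxia-inducible factors HIF1A and EPAS1 and of the aryl hydrocarbon receptor AHR. Parental cells, clone A and clone B were each kept for 48 hours under 3 conditions, with 3 replicates per group. The conditions were normoxia (20% O2) in regular medium, hypoxia (1% O2) in regular medium, and hypoxia in TIFM (Tumor Interstitial Fluid Medium), a medium formulated after the nutrient levels of pancreatic tumor interstitial fluid. TIFM was given only under hypoxia, so its effect was compared within hypoxia.

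Values in the table deposited by the authors are raw read counts per gene. The submitters' processing notes name HISAT2 for alignment, featureCounts for counting and GRCh38 as the genome; versions and settings are not given in the sources used here. The table was tested on its values: all entries were whole numbers, and each library's values summed to between 26057022 and 38341713 counts (median 31727174). It held 21487 Ensembl gene identifiers. The annotation used here (GENCODE v29, GRCh38) gave a symbol to 21383 of them and none to 104, and 15 shared a symbol with another identifier. Exons shared by overlapping genes on that annotation are given as a percentage beside some of the genes concerned, because counts there can belong to either gene. Other named genes with shared exons include HDGFL3 (6.35%), FADS2 (4.89%) and PFKFB4 (4.73%). A gene without a percentage is not thereby free of overlap.

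All 27 libraries went into a single fit with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the group factor (minimum count 10, minimum total count 15), which left 13943 tested genes; 3417 had no count in any library. Library sizes were scaled with TMM factors. The design had 1 coefficient for each of the 9 groups, and dispersions and quasi-likelihood F tests were robust. The common dispersion was 0.0199, a biological coefficient of variation of 14.1%. In separate estimates by condition it was 7.03% in normoxia, 9.6% in hypoxia and 22% in hypoxia with TIFM, and by group it was highest in clone A in TIFM (29.2%). Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes, separately for each of 17 contrasts: hypoxia in each genotype, TIFM under hypoxia in each genotype, each clone against parental in each condition, the difference of each clone's response from the parental response to hypoxia and to TIFM, and the difference of the hypoxia response between the clones. A gene counted as called in both clones when both contrasts passed with the same sign. Fold changes are log2 values with the standard error of the fit, and levels are TMM-scaled CPM (counts scaled to a common library total) with SD, n = 3 per group unless stated. For genes with 1 to 3 counts in a whole group the ratio is given with its 95% counting interval (exact binomial), and for a group at 0 counts the fold is a lower bound against 3 counts over the group; these cover counting error only, since reads carry no molecular identifiers.

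Gene lists were tested with camera of limma 3.58.1 with a preset inter-gene correlation of 0.01, adjusted over the 26 lists within each contrast. The lists, with measured of listed genes, were HIF pathway components (9 of 12), glycolysis and glucose uptake (21 of 23), canonical HIF targets outside glycolysis (38 of 40), AHR targets (9 of 14), the ATF4 and amino acid response (33 of 35), arginine and proline metabolism (13 of 16), cholesterol synthesis and uptake (22 of 25), fatty acid synthesis and desaturation (15 of 16), the unfolded protein response (20 of 20), NRF2 targets (18 of 20), interferon-stimulated genes (19 of 25), MHC class I presentation (14 of 17), inflammatory cytokines and NF-kB targets (18 of 25), mitosis (23 of 25), DNA replication (31 of 31), mitochondrial DNA-encoded transcripts (13 of 13), the nuclear-encoded respiratory chain (40 of 45), cytosolic ribosomal proteins (44 of 46), ribosome biogenesis (22 of 25), metallothioneins and zinc response (8 of 10), collagens and matrix (24 of 24), the mesenchymal state (17 of 18), epithelial and classical pancreatic cancer markers (21 of 24), basal-like keratin and squamous markers (4 of 14), autophagy and lysosome (19 of 20), and markers of cells of other types (9 of 21). Some genes stand on several lists, so the lists are not independent. STC2, for example, is among HIF targets, AHR targets and ATF4 genes, and DDIT4 among HIF targets and ATF4 genes. A list count gives members called over all genes tested, followed by the count adjusted over the list alone where the 2 differ. Where none follows, it was the same.

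The comparisons, tests, gene lists, first set of alternatives and rule for named genes were fixed before the data were examined. The rule always names ARNT, HIF1A, EPAS1, CA9, VEGFA, SLC2A1, PDK1, ADM, NDRG1, CYP1B1, TIPARP, ASNS and ASS1. For each comparison of 2 groups it adds the 5 genes with the largest rise and the 5 with the largest fall among called genes with a mean of at least 5 CPM in a group and no overlap between the 3 libraries of each group. It also adds up to 4 members of each list with the largest change, and 10 genes per direction for results shared by both clones, ranked by the smaller change. Genes named in one comparison are followed through others, and the text gives a selection.

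The replicate numbers are not stated to mark shared cultures or days. Across 8889 genes, deviations from the group mean were correlated between libraries of the same number; all 3 correlations were above 0.1 in 1 of 12 comparisons, clone B against parental in hypoxia with TIFM (0.22, 0.34 and 0.24), so no block was used in the fit and a block was run as an alternative. The pipeline was tested on simulated counts. With parental hypoxia as the contrast, edgeR recovered 25.4%, 90.1% and 100% of genes changed by log2 values of 0.5, 1 and 2, and 6.45% of its calls were unchanged genes. For TIFM in clone A these were 18.2%, 69.1% and 98.5% with 7.46% unchanged, and for the difference of the hypoxia response of clone A they were 5.08%, 65.3% and 92.8% with 1.72% unchanged. DESeq2 1.42.0 had 11% to 20.4% unchanged genes among its calls in the same data. All simulated libraries took their dispersions from the fit of the 27 libraries (14.1% in common). The real clone A TIFM libraries spread more (29.2%), so the figures for TIFM in clone A do not cover their spread. Camera called the 1 raised list and 0 of 25 untouched lists. Because both clones share the parental controls, 5 data sets with no genotype difference were also simulated for each result on both clones. With no difference put in, few calls are expected in either clone. A simulated count of 0 in both therefore does not measure how far shared controls raise the overlap of real calls.

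Alternatives were RLE factors in place of TMM, DESeq2, no filter, a stricter filter (at least 1 CPM in 3 libraries and a mean of 10 counts), the replicate number as a block, a fit with only the libraries of the groups compared, leaving out each library in turn, camera with an estimated correlation, and fry. A per-library correction for transcript GC content, alone and with the block, was added after seeing the data. Other groupings of the same libraries were tested for each count.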

Results

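Gene expression was measured by polyA RNA sequencing in 27 libraries of Panc1 cells, which fell into 9 groups of 3. Parental cells and 2 ARNT-knockout clones, called clone A and clone B here, were each grown for 48 hours in normoxia (20% O2), in hypoxia (1% O2), or in hypoxia with TIFM, a medium modelled on the interstitial fluid of pancreatic tumors. The labels state the purpose as the effect of ARNT on the hypoxic response. Libraries held between 26057022 and 38341713 counts, with a median of 31727174. No label says that the 3 replicates of a group were separate cultures, so p-values measure only the spread between these libraries.

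ARNT itself (chromosome 1, 150809705 to 150876768, minus strand, GRCh38) was transcribed in every library. Its level in normoxia was 71.2 ± 3.62 CPM (SD, n = 3) in parental cells, 75.5 ± 2.19 in clone A and 63.9 ± 1.44 in clone B. In hypoxia ARNT stood at 71.4 ± 3.45, 68.5 ± 0.331 and 64.8 ± 3.0 CPM in the same order. In hypoxia with TIFM it stood at 63.9 ± 4.51, 55.3 ± 4.26 and 48.8 ± 3.85 CPM. In normoxia ARNT did not differ detectably from parental cells in clone A (log2 0.08, adjusted p = 0.498) or clone B (−0.16, adjusted p = 0.199). A count of transcripts does not check the knockout, since an edited gene can still be transcribed.

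Hypoxia in parental cells raised VEGFA and genes of glucose uptake and glycolysis. VEGFA, the vascular growth factor (chromosome 6, 43770184 to 43786487), went from 55.7 ± 2.24 to 386 ± 8.45 CPM (SD, n = 3), a log2 change of 2.79 ± 0.14 (SE, adjusted p = 1.64e-13). The glucose transporter SLC2A1 (chromosome 1, 42925375 to 42959176) rose by 2.79 ± 0.16 to 139 ± 13.5 CPM. PDK1, a kinase that restrains pyruvate dehydrogenase, rose by 3.29 ± 0.18 to 175 ± 11.5 CPM. NDRG1, a stress-response gene (chromosome 8, 133237171 to 133302022), rose by 3.67 ± 0.18 to 90.9 ± 2.51 CPM. ADM, which encodes adrenomedullin, rose by 1.54 ± 0.14, and EPAS1, the HIF2A subunit, by 1.02 ± 0.14. CA9, a carbonic anhydrase, rose by 3.90 ± 0.73 but reached only 0.943 ± 0.123 CPM, and 38.5% of its exon length is shared with ARHGEF39. Transcripts of HIF1A (chromosome 14, 61695513 to 61748259) fell by 0.68 ± 0.16 (adjusted p = 0.00221).

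Of 13943 tested genes, edgeR called 4212 for hypoxia in parental cells, 2141 higher and 2071 lower. Among them 885 rose and 249 fell by at least 2-fold. Among called genes with a mean of at least 5 CPM in a group and no overlap between the 3 libraries of each group, the largest rises were PPFIA4 (3.89 ± 0.24), NDRG1, PPP1R3C (3.63 ± 0.23), a glycogen-targeting phosphatase subunit, ANGPTL4 (3.61 ± 0.29), an inhibitor of lipoprotein lipase, and PFKFB4 (3.49 ± 0.17), a regulator of glycolysis. Within the same limits the largest falls were RCSD1 (−2.12 ± 0.26), DCN (−1.66 ± 0.60), RET (−1.65 ± 0.15), a receptor tyrosine kinase, CDCA7 (−1.63 ± 0.22) and DSCC1 (−1.54 ± 0.17), which acts in sister chromatid cohesion. DCN lost its call without 4 of the 6 libraries and with DESeq2. A fit with only the libraries compared called 6804 genes for hypoxia in parental cells.

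Canonical HIF targets outside glycolysis rose in 35 of 38 members in parental hypoxia and in 36 adjusted over the list alone (median log2 1.97, camera adjusted p = 7.31e-103). STC2, stanniocalcin 2, rose by 2.78 ± 0.09. Glycolysis and glucose uptake rose in 20 of 21 (median 1.31, adjusted p = 2.2e-42), among them SLC2A3 (3.17) and HK2 (2.98 ± 0.17), hexokinase 2. The ATF4 and amino acid response rose in 22 of 33 (median 0.95, adjusted p = 6.54e-22), with DDIT4 at 2.18, VLDLR at 1.85 and ASNS, the asparagine synthetase, at 1.63 ± 0.13. DDIT4 is also on the HIF target list, and STC2 is on the HIF target, ATF4 and AHR lists. AHR targets rose in 5 of 9 and in 6 adjusted over the list alone (median 1.36, adjusted p = 1.36e-07), with CYP1B1 at 1.17 ± 0.23 and TIPARP at 1.36 ± 0.10. These 4 lists kept their calls with an estimated correlation. Across all comparisons 177 list calls were made with the preset correlation, and 64 held with an estimated one.

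Genes of cell division fell together in parental hypoxia with the preset correlation. Mitosis genes fell in 22 of 23 (median −0.78, adjusted p = 3.38e-12, but adjusted p = 0.0734 with an estimated correlation), with TOP2A at −1.18 ± 0.19, AURKB at −1.10 and BUB1 at −1.10. DNA replication genes fell in 29 of 31 (median −0.81, adjusted p = 3.72e-19, but adjusted p = 0.0526 with an estimated correlation), with MCM10 at −1.45 ± 0.18 and GINS2 at −1.22. Cholesterol synthesis rose in 13 of 22 and in 14 adjusted over the list alone (median 0.41, adjusted p = 0.00432, but adjusted p = 0.275 with an estimated correlation), with INSIG1 at 1.08. Fatty acid synthesis rose in 8 of 15 and fell in 2, or 3 adjusted over the list alone (median 0.45, adjusted p = 0.007, but adjusted p = 0.325 with an estimated correlation), with SCD, the stearoyl-CoA desaturase, at 1.31 ± 0.14. Ribosome biogenesis fell in 9 of 22, or 10 adjusted over the list alone, and rose in 1 (median −0.37, adjusted p = 0.007, but adjusted p = 0.54 with an estimated correlation). The other 17 lists were not called. Among these, HIF pathway components had a median of −0.06 and a mean of 0.33 (adjusted p = 0.0728). Markers of cells of other types rose in 2 of 9, or 3 adjusted over the list alone, and fell in 1 (adjusted p = 0.499).

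**Figure D1:**
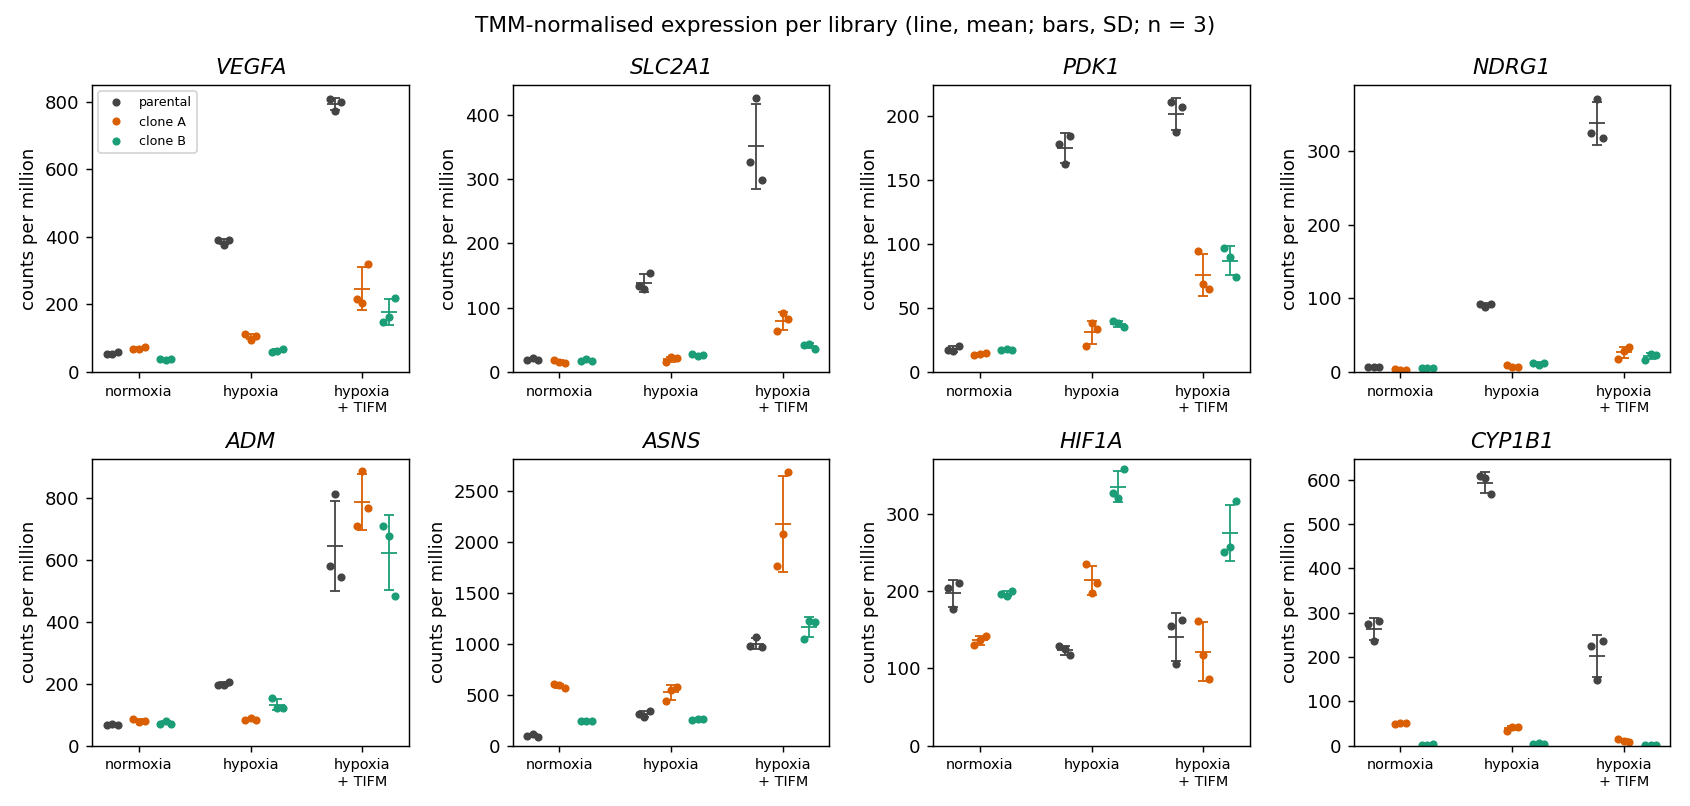
TMM-scaled CPM (y axis) of 8 genes in each library, by condition (x axis) and genotype, with points for libraries, lines for means and bars for SD (n = 3). VEGFA in hypoxia sits at 386 ± 8.45 CPM in parental cells against 105 ± 8.28 in clone A and 62.4 ± 4.43 in clone B.

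Hypoxia raised the HIF-responsive genes in the clones far less. For hypoxia in clone A, VEGFA rose from 69.7 ± 3.67 to 105 ± 8.28 CPM (n = 3, log2 0.59 ± 0.13), PDK1 by 1.15 ± 0.17 and NDRG1 by 1.22 ± 0.19. SLC2A1 (0.32 ± 0.15, adjusted p = 0.145) and ADM (0.07 ± 0.14) did not pass there. For hypoxia in clone B, VEGFA rose by 0.73 ± 0.14, PDK1 by 1.11 ± 0.17, NDRG1 by 1.15 ± 0.18 and ADM by 0.84 ± 0.14. SLC2A1 rose in clone B by 0.57 ± 0.15 (adjusted p = 0.0196), a call lost without 4 of the 6 libraries. HIF1A transcripts rose in both clones, by 0.65 ± 0.16 in clone A (adjusted p = 0.00484) and 0.77 ± 0.16 in clone B (adjusted p = 0.00347).

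Hypoxia in clone A was called for 3097 genes, 1453 higher and 1644 lower. Genes that rose included RAB17 (3.81 ± 0.74), a small GTPase, HID1 (3.68 ± 0.54), IL22RA1 (2.78 ± 0.68) and the chemokine CCL2 (2.63 ± 0.69). CCL2 was lost without clone A hypoxia replicate 1 (adjusted p = 0.0581). Genes that fell included FOSL1 (−1.70 ± 0.31), an AP-1 subunit, EDN1 (−1.61 ± 0.19), the endothelin-1 gene, MT1E (−1.54 ± 0.23), a metallothionein, and RRS1 (−1.40 ± 0.21), a ribosome biogenesis factor. RRS1 shares 11.4% of its exon length with ENSG00000285655. The count for hypoxia in clone A fell to 1916 without clone A hypoxia replicate 1 and to 2054 without clone A normoxia replicate 2, and was 4860 with only the libraries compared.

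Hypoxia in clone B was called for 1297 genes, 622 higher and 675 lower. CCL2 (2.81 ± 0.55), ZNF114 (2.17 ± 0.32), HID1 (1.98 ± 0.51), SLCO4C1 (1.95 ± 0.34), an organic anion transporter, and ITGB8 (1.85 ± 0.43), an integrin subunit, rose. HID1 lost its call without 4 of the 6 libraries. TXNIP (−2.47 ± 0.29), which restrains thioredoxin and glucose uptake, and GJB2 (−1.55 ± 0.16), a gap junction subunit, fell. The count for hypoxia in clone B fell to 817 and 527 without clone B hypoxia replicates 2 and 3, and to 551, 580 and 627 without clone B normoxia replicates 1, 2 and 3. With only the libraries compared it was 4242.

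Canonical HIF targets still rose in hypoxia in both clones. In clone A 20 of 38 rose and 1 fell, or 21 and 2 adjusted over the list alone (median 0.42, adjusted p = 2.24e-10), with ANKRD37 at 1.62 ± 0.21 and PLOD2, a collagen lysyl hydroxylase, at 1.30. ANKRD37 shares 35.2% of its exon length with UFSP2. In clone B 16 rose and 1 fell, or 21 and 4 adjusted over the list alone (median 0.32, adjusted p = 9.2e-11). In clone A cholesterol synthesis rose in 14 of 22, or 16 adjusted over the list alone (median 0.47, adjusted p = 2.51e-07), and the unfolded protein response fell in 8 of 20, or 10 adjusted over the list alone (median −0.28, adjusted p = 0.000709). These 4 calls held with an estimated correlation. The same lists moved the same way in clone B, where cholesterol synthesis rose in 3 (median 0.21, adjusted p = 0.00179, but adjusted p = 0.336 with an estimated correlation). There the unfolded protein response fell in 5, or 8 adjusted over the list alone (median −0.19, adjusted p = 0.00933, but adjusted p = 0.172 with an estimated correlation). DNA replication fell in 11 of 31 in clone A and 5 in clone B, or 13 and 12 adjusted over the list alone (medians −0.30 and −0.25, adjusted p = 2.52e-06 and 2.26e-05). With an estimated correlation these had adjusted p = 0.538 and 0.408. ATF4 targets rose in 7 of 33 in clone B (median 0.15, adjusted p = 0.0036, but adjusted p = 0.465 with an estimated correlation). Glycolysis rose in 4 of 21 in clone A, or 6 with 4 lower adjusted over the list alone (median 0.25, adjusted p = 0.0301, lost without 3 of 6 libraries, and adjusted p = 0.578 with an estimated correlation). In clone B it rose in 6, or 9 with 1 lower adjusted over the list alone (median 0.23, adjusted p = 0.000721, but adjusted p = 0.362 with an estimated correlation). Mitochondrial DNA-encoded transcripts fell in clone B in 5 of 13, or 10 adjusted over the list alone (median −0.49, adjusted p = 1.04e-05, but adjusted p = 0.362 with an estimated correlation). Metallothioneins fell in clone B in 2 of 8, or 3 adjusted over the list alone (adjusted p = 0.0189, 0.102 without clone B hypoxia replicate 3, and adjusted p = 0.282 with an estimated correlation). Inflammatory genes rose in clone B in 3 of 18, with 1 lower adjusted over the list alone (adjusted p = 0.0205, 0.288 without clone B hypoxia replicate 1, and adjusted p = 0.362 with an estimated correlation).

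The difference between each clone's hypoxia response and the parental one was tested directly. VEGFA differed by −2.20 ± 0.19 in clone A and −2.06 ± 0.19 in clone B, and SLC2A1 by −2.47 ± 0.22 and −2.22 ± 0.22. PDK1 differed by −2.14 and −2.18, and NDRG1 by −2.44 and −2.52. ASNS, which rose in parental hypoxia, differed by −1.80 and −1.55, and EPAS1 by −1.10 and −0.83. In normoxia ASNS already stood higher in clone A (569 to 602.8 CPM) and clone B (241.2 to 247.8) than in parental cells (89.23 to 115.2). Its smaller response thus started from a raised level. HIF1A differed upward, by 1.33 ± 0.23 in clone A (adjusted p = 0.00039) and 1.44 ± 0.23 in clone B (adjusted p = 0.000159). ADM differed by −1.47 ± 0.20 in clone A and −0.71 ± 0.19 in clone B, where the call was lost without any of 11 of the 12 libraries. CYP1B1 differed in clone A (−1.53) and did not pass in clone B (−0.28, adjusted p = 0.795). In clone B CYP1B1 stood at only 1.83 to 3.69 CPM in normoxia and 3.18 to 6.72 CPM in hypoxia. Parental cells in hypoxia held 567 to 609 CPM, so the clone B ratio rests on very low levels.

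The hypoxia response of clone A minus parental was called for 869 genes, 306 higher and 563 lower, and the hypoxia response of clone B minus parental for 660, 208 higher and 452 lower. In clone A 3 of 21 splits of the libraries gave as many genes (highest other 3694), and in clone B 1 of 21, the real one. The splits mixed parental and clone libraries separately in each condition. Differences between genotypes thus enter their counts, so they cannot decide on chance. The hypoxia response of both clones minus parental had 438 genes with the same sign, 121 higher and 317 lower, and 0 with opposite signs. From the separate counts 4.56 and 18.3 would be shared. Shared lower responses included PPP1R3C (−3.51 in clone A and −3.86 in clone B), GNG4 (−3.24 and −3.01), a G protein subunit, FAM13A (−2.86 and −2.84), NPR3 (−2.80 and −3.01), the natriuretic peptide clearance receptor, ANGPTL4 (−3.31 and −2.65) and HK2 (−3.38 and −2.52). Shared higher ones included GREM1 (1.80 and 2.23), a BMP antagonist, LAMA3 (1.85 and 1.74), a laminin chain, TBX2 (2.22 and 1.55), CDH1 (1.42 and 1.60), the epithelial cadherin, and SPARC (1.18 and 1.42). GREM1 in clone A, LAMA3 in both clones and TBX2 in clone B lost their calls without 2 to 6 of the 12 libraries. CDH1 in both clones, and LAMA3 and SPARC in clone A, stood far below parental cells in normoxia, as given further below. A higher response of these genes is a difference of log2 ratios and does not mean a level above parental cells.

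Simulated data with shared controls and no genotype difference gave 0 genes called in both. With no difference put in, few calls are expected in either clone, so this 0 says little about the overlap. Across genes the covariance of the 2 hypoxia differences was 0.292 and the correlation 0.646, against 0.0855 and 0.487 in the simulations. The simulations already hold the shared parental libraries, at a common spread of 14.1%. The real ones spread by 9.83% in normoxia and 5.01% in hypoxia. Spread between those libraries is thus argued against as the source of a covariance that large. The 3 parental libraries of each condition were too few to give each clone at least 2 of its own, so shared controls may still add to the number of genes shared. With only the libraries compared, the hypoxia response of clone A minus parental gave 2656 genes, the hypoxia response of clone B minus parental 2592 and the hypoxia response of both clones minus parental 1578. Without parental hypoxia replicate 1 the count in both was 288.

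Canonical HIF targets responded less to hypoxia in 30 of 38 in clone A, or 35 adjusted over the list alone (median −1.52, adjusted p = 1.12e-75). In clone B 33 responded less, or 35 adjusted over the list alone (adjusted p = 9.79e-105). Glycolysis responded less in 15 of 21 in clone A and 16 in clone B, or 17 and 19 adjusted over the list alone (medians −1.14 in each, adjusted p = 7.17e-44 and 6.21e-48). ATF4 targets responded less in 18 of 33 and 15, or 26 and 19 adjusted over the list alone (medians −0.86 and −0.65, adjusted p = 1.56e-30 and 2.2e-22). Most members of the ATF4 list already stood higher in both clones in normoxia, as given further below. AHR targets responded less in 3 of 9 in each clone, with 4 in clone A adjusted over the list alone (adjusted p = 6.72e-08 and 6.36e-08). Mitosis genes differed upward in 15 of 23 in clone A, or 22 adjusted over the list alone (median 1.03, adjusted p = 6.22e-22). These 9 calls held with an estimated correlation. Mitosis in clone B differed upward in 6, or 18 adjusted over the list alone (median 0.71, adjusted p = 2.67e-12, but adjusted p = 0.0898 with an estimated correlation). DNA replication differed upward in 11 of 31 and downward in 1 in clone A, or 19 and 1 adjusted over the list alone (median 0.60, adjusted p = 8.53e-09, but adjusted p = 0.222 with an estimated correlation). In clone B it differed upward in 8, or 22 adjusted over the list alone (median 0.57, adjusted p = 5.71e-14, but adjusted p = 0.0969 with an estimated correlation). NRF2 targets differed downward in clone A in 3 of 18, or 4 adjusted over the list alone (adjusted p = 0.018, lost without 4 of 12 libraries, and adjusted p = 0.215 with an estimated correlation).

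Of the 885 genes that rose at least 2-fold in parental hypoxia, 194 had a smaller response called in both clones and 123 in 1 clone. Of the same 885 genes, 170 were called higher in hypoxia in both clones and 481 in neither. These genes were chosen for their rise in parental cells, and such a choice alone favours smaller responses elsewhere. Of the 249 genes that fell at least 2-fold, 33 had a smaller response in both clones and 59 were called lower in both. In all 3 genotypes 306 genes rose and 374 fell, against 9.95 and 11.8 expected from the separate counts. FBP2, a gluconeogenic phosphatase, rose by 2.28 in parental cells, 1.97 in clone A and 2.02 in clone B, SLCO4C1 by 2.91, 1.86 and 1.95, and ITGB8 by 1.61, 2.37 and 1.85. GPRC5C changed by −1.15, −1.46 and −1.31, LONRF2 by −1.50, −1.14 and −1.44, and ANPEP, aminopeptidase N, by −1.15, −1.21 and −1.08.

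The hypoxia response of clone B minus clone A was called for 0 genes by edgeR with all 27 libraries, with 870 at an unadjusted p under 0.05. Other settings called some, 36 with DESeq2, 57 by edgeR with only the libraries compared and 1 with the GC correction. ADM had a difference of 0.77 (adjusted p = 0.267) and CYP1B1 of 1.25 (adjusted p = 0.361). Camera called 7 lists, none of which held with an estimated correlation. For mitosis the median was −0.31 (adjusted p = 8.08e-06, but adjusted p = 0.371 with an estimated correlation), and for fatty acid synthesis −0.34 (adjusted p = 1.56e-05, but adjusted p = 0.213 with an estimated correlation), with 0 of 15 members called and 5 adjusted over the list alone.

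TIFM under hypoxia lowered sterol and fatty acid synthesis genes in parental cells and raised amino acid response genes. FADS2, a fatty acid desaturase, fell from 660 to 45.2 CPM (n = 3, log2 −3.87 ± 0.15). STARD4, a sterol carrier, fell by 3.30 ± 0.21 and INSIG1, a sterol sensor, by 2.90 ± 0.17. ASNS rose from 310.3 ± 29.2 to 1002 ± 53.4 CPM (log2 1.69 ± 0.13), and ASS1, argininosuccinate synthase, from 18.5 to 71.7 ± 7.09 CPM (1.96 ± 0.15). VEGFA rose further, to 793 ± 18.3 CPM (1.04 ± 0.13), as did SLC2A1 (1.34 ± 0.15), ADM (1.70 ± 0.14) and NDRG1 (1.89 ± 0.17). PDK1 did not pass (0.21 ± 0.16, adjusted p = 0.311), and CYP1B1 fell by 1.55 ± 0.23.

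In parental cells 5881 genes were called with TIFM, 3033 higher and 2848 lower. Large rises included DHRS2 (4.57 ± 0.28), a dehydrogenase, S100P (4.39 ± 0.23), a calcium-binding protein, TXNIP (4.18 ± 0.30) and CCNP (3.61 ± 0.32). SLCO4C1 was among the large falls (−3.46 ± 0.36). APOB, the main protein of liver lipoproteins, had 504 counts over the TIFM group against 1 in hypoxia (ratio 656, 95% counting interval 117 to 26000). Parental TIFM replicates 1 to 3 held 83, 16 and 405 of these counts, so the ratio rests mostly on replicate 3. APOB and other liver transcripts, 9 genes summed, stood at 8.04 CPM or more in 6 of the 27 libraries, including all 3 parental TIFM libraries, and at 0.379 CPM or less in the others.

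Cholesterol synthesis and uptake fell with TIFM in 21 of 22 in parental cells (median −1.93, adjusted p = 1.28e-52). Fatty acid synthesis fell in 10 of 15, with 1 higher adjusted over the list alone (median −1.21, adjusted p = 2.63e-21), and ACLY stood at −2.52. The ATF4 and amino acid response rose in 30 of 33, or 31 adjusted over the list alone (median 1.32, adjusted p = 5.05e-32), with CTH, cystathionine gamma-lyase, at 2.79 and SLC7A11, the cystine transporter, at 2.23. The unfolded protein response rose in 11 of 20, or 12 adjusted over the list alone, and fell in 3 (median 0.33, adjusted p = 0.000376), with XBP1 at 1.59. Arginine and proline metabolism rose in 7 of 13 and fell in 3 (median 0.76, adjusted p = 0.013). These 5 calls held with an estimated correlation. Cytosolic ribosomal proteins rose in 34 of 44, or 35 adjusted over the list alone (median 0.59, adjusted p = 8.75e-09, but adjusted p = 0.476 with an estimated correlation). DNA replication rose in 19 of 31 and fell in 2 (median 0.50, adjusted p = 0.000126, but adjusted p = 0.476 with an estimated correlation). HIF targets rose in 16 of 38, or 17 adjusted over the list alone, and fell in 9 (median 0.24, adjusted p = 0.0247, but adjusted p = 0.0926 with an estimated correlation). Glycolysis fell in 12 and rose in 3 without passing as a list (median −0.50, adjusted p = 0.0698).

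**Figure D2:**
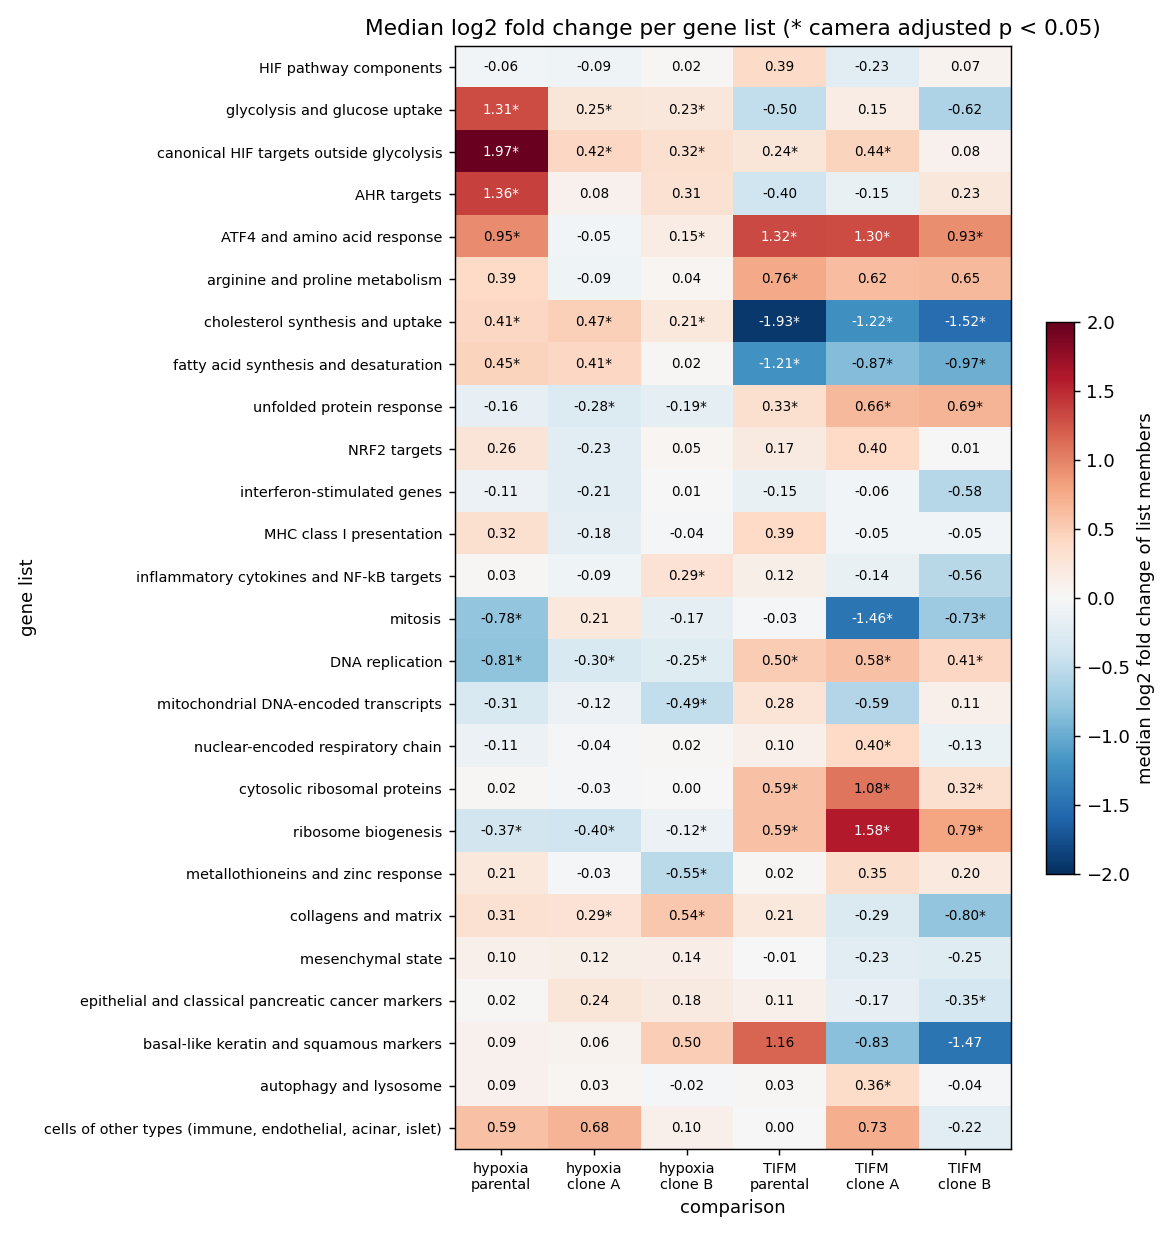
Median log2 fold change of the members of each of the 26 gene lists (y axis) for hypoxia and for TIFM under hypoxia in parental cells, clone A and clone B (x axis), with colour from −2 to 2 and an asterisk for a camera adjusted p under 0.05. HIF targets outside glycolysis stood at 1.97, 0.42 and 0.32 for hypoxia in parental cells, clone A and clone B, and cholesterol synthesis at −1.93, −1.22 and −1.52 for TIFM.

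TIFM raised ASNS and TXNIP and lowered FADS2 and STARD4 in the clones as well. In clone A ASNS went from 523 ± 71.2 to 2175 ± 471 CPM (n = 3, log2 2.06 ± 0.13), TXNIP rose by 5.86 ± 0.32, DHRS2 by 6.49 ± 0.34 and NPC1L1, a sterol transporter, by 5.25 ± 0.44. STOX1 (−4.98 ± 0.27), ITGB8 (−4.80 ± 0.65) and PIF1 (−4.63 ± 0.24), a DNA helicase, fell in clone A. In clone B ASNS rose by 2.17 ± 0.13, TXNIP by 3.92 ± 0.30 and STKLD1 by 3.79 ± 0.24. POSTN, the matrix protein periostin (−3.94 ± 0.60), FADS2 (−3.31 ± 0.15) and CACNA1G, a calcium channel subunit (−3.30 ± 0.26), fell there. VEGFA rose by 1.23 ± 0.14 in clone A and 1.51 ± 0.14 in clone B, PDK1 by 1.29 ± 0.16 and 1.21 ± 0.16, and ADM by 3.21 ± 0.15 and 2.24 ± 0.14. ARNT fell in clone A (−0.31 ± 0.09, adjusted p = 0.00297) and clone B (−0.41 ± 0.09, adjusted p = 0.000298) and did not pass in parental cells (−0.16, adjusted p = 0.136).

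With TIFM 9368 genes were called in clone A, 4596 higher and 4772 lower, and 7490 in clone B, 3605 higher and 3885 lower. SIGLEC1 in clone A had 477 counts over the TIFM group against 1 in hypoxia (ratio 620, 95% counting interval 111 to 24500), and ASTL had 362 against 0, at least 157-fold higher. In all 3 genotypes 1950 genes rose and 1855 fell, against 258 and 272 expected from the separate counts. NPC1L1 rose by 5.18 in parental cells and 4.20 in clone B, CTH by 2.79, 3.32 and 2.68 in parental cells, clone A and clone B, and S100P by 4.39, 5.12 and 2.50. FADS2 changed by −3.87, −3.04 and −3.31, STARD4 by −3.30, −3.51 and −2.91, and TM7SF2, a sterol reductase, by −2.88, −3.19 and −3.16.

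The unfolded protein response rose with TIFM in 14 of 20 and fell in 2 in clone A (median 0.66, adjusted p = 3.36e-05), with HERPUD1 at 3.19 ± 0.11 and XBP1 at 3.05. In clone B it rose in 16 and fell in 1 (median 0.69, adjusted p = 1.35e-08). Cholesterol synthesis fell in 21 of 22 in clone B (median −1.52, adjusted p = 1.36e-21). These 3 calls held with an estimated correlation. In clone A cholesterol synthesis fell in 17 and rose in 3 (median −1.22, adjusted p = 9.85e-07, but adjusted p = 0.0965 with an estimated correlation). ATF4 targets rose in 26 of 33 in clone A and 27 in clone B, with 1 lower in each (medians 1.30 and 0.93, adjusted p = 3.43e-12 and 1.57e-16). With an estimated correlation these had adjusted p = 0.0965 and 0.0566. Mitosis fell in 19 of 23 and rose in 1 in clone A (median −1.46, adjusted p = 9.85e-07, but adjusted p = 0.275 with an estimated correlation), with CCNB1 at −2.63. In clone B it fell in 14, or 15 adjusted over the list alone, and rose in 1 (median −0.73, adjusted p = 7.67e-05, but adjusted p = 0.326 with an estimated correlation). Ribosome biogenesis rose in 20 of 22 and fell in 1 in clone A (median 1.58, adjusted p = 4.36e-10, but adjusted p = 0.0965 with an estimated correlation), and rose in 17 and fell in 1 in clone B (median 0.79, adjusted p = 3.11e-06, but adjusted p = 0.24 with an estimated correlation). The respiratory chain rose in 24 of 40 and fell in 2 in clone A (adjusted p = 0.0178, 0.0602 without clone A TIFM replicate 3, and adjusted p = 0.575 with an estimated correlation). Autophagy genes rose in 9 of 19 and fell in 2 in clone A (adjusted p = 0.0225, but adjusted p = 0.52 with an estimated correlation).

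Single genes differed in their TIFM response between the clones and parental cells. PDK1 differed by 1.09 in clone A. A larger rise of PDK1 was not particular to that clone. In clone B it went from 34.89 to 39.82 CPM in hypoxia to 74.37 to 97.24 CPM with TIFM. Parental cells held 162.2 to 184.3 and 187.6 to 210.6 CPM. HMOX1, heme oxygenase, differed by 3.99 ± 0.35 in clone A, and POSTN by −4.11 in clone B. VEGFA did not pass in clone A (0.19, adjusted p = 0.452) or clone B (0.47, adjusted p = 0.113), nor did ASNS (0.36, adjusted p = 0.103, and 0.48, adjusted p = 0.084). SLC2A1 differed in opposite directions, by 0.65 in clone A and −0.74 in clone B, calls lost without 4 and 5 of the 12 libraries. Both clones differed upward for KLF10 (2.92 and 1.68), a TGF-beta-inducible factor, BMF (2.65 and 1.53), a pro-apoptotic BCL2-family member, and MFSD2A (2.98 and 1.45). Both differed downward for RASSF4 (−2.67 and −2.79), NEURL1B (−3.42 and −1.98), AZIN2 (−2.21 and −1.94), an antizyme inhibitor, and PGF (−2.38 and −1.88), placental growth factor. RASSF4 shares 7.33% of its exon length with DEPP1.

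The TIFM response of clone A minus parental was called for 5426 genes, 2691 higher and 2735 lower, and for 3539 with only the libraries compared. The TIFM response of clone B minus parental was called for 1450, 566 higher and 884 lower, and for 933 without parental hypoxia replicate 1. For that count 7 of 21 splits of the libraries gave as many genes (highest other 4544). Such splits mix parental and clone libraries, so differences between genotypes enter them and they cannot decide on chance. The TIFM response of both clones minus parental had 880 genes with the same sign, 371 higher and 509 lower, and 30 with opposite signs, against 109 and 173 expected from the separate counts. With only the libraries compared it had 370 and with the GC correction 1368, and 2 of 21 splits of the libraries gave as many genes (highest other 1301). Simulated shared controls with no genotype difference gave 0 genes, which again says little about the overlap. The observed correlation across genes (0.387) lay below the simulated one (0.484), and the covariance (0.283) above it (0.0827). The 3 parental libraries per condition were too few to give each clone at least 2 of its own, so part of the excess may come from shared controls.

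The unfolded protein response differed upward with TIFM in 6 of 20 in clone B, or 10 adjusted over the list alone (median 0.38, adjusted p = 9.37e-06), and held with an estimated correlation. In clone A it differed upward in 8 (median 0.31, adjusted p = 0.00338, but adjusted p = 0.0792 with an estimated correlation). Cholesterol synthesis differed upward in 16 of 22 in clone A (median 0.67, adjusted p = 2.49e-07, but adjusted p = 0.0792 with an estimated correlation). In clone B it differed upward in 7 and downward in 1, or 9 and 1 adjusted over the list alone (median 0.42, adjusted p = 2.07e-05, but adjusted p = 0.0775 with an estimated correlation). Mitosis differed downward in 19 of 23 in clone A (median −1.33, adjusted p = 5.12e-11, but adjusted p = 0.138 with an estimated correlation), and in 9 in clone B, or 16 adjusted over the list alone (median −0.70, adjusted p = 2.91e-09, but adjusted p = 0.113 with an estimated correlation). Collagens differed downward in 12 of 24 in clone B, or 16 adjusted over the list alone (median −1.03, adjusted p = 7.41e-09, but adjusted p = 0.0521 with an estimated correlation), and in 8 in clone A (median −0.45, adjusted p = 0.0292, lost without 3 of 12 libraries, and adjusted p = 0.455 with an estimated correlation). Mesenchymal genes differed downward in 6 of 17 and upward in 1 in clone B (adjusted p = 0.0322, lost without 3 of 12 libraries, and adjusted p = 0.219 with an estimated correlation). Basal-like markers differed downward in 2 of 4 in clone B, or 3 adjusted over the list alone (adjusted p = 0.000478, but adjusted p = 0.0521 with an estimated correlation). Of the 12 lists called in clone A and 13 in clone B, the unfolded protein response in clone B was the 1 call that held.

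In normoxia both clones already differed from parental cells in CDH1, EGLN3, CYP1B1 and ASNS. CDH1 was lower by −5.21 ± 0.18 in clone A and −5.57 ± 0.18 in clone B, and EGLN3, a HIF prolyl hydroxylase, by −4.77 ± 0.23 and −4.78. CYP1B1, an AHR-inducible enzyme, stood at 264 ± 24.8 CPM in parental cells, 50.3 ± 0.269 in clone A (−2.39 ± 0.24) and 2.45 ± 1.07 in clone B (−6.75 ± 0.30). ASNS stood at 100.4 ± 13.3 CPM in parental cells, 589 ± 17.9 in clone A (2.55 ± 0.13) and 244 ± 3.29 in clone B (1.28 ± 0.13). HIF1A was lower in clone A (−0.53 ± 0.16). VEGFA did not pass in clone A (0.33, adjusted p = 0.0676) and was lower in clone B (−0.57 ± 0.14).

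For clone A against parental in normoxia 4408 genes were called, 2210 higher and 2198 lower. SLC6A15 (6.19 ± 0.26), a neutral amino acid transporter, BCAT1 (5.29 ± 0.17), a branched-chain aminotransferase, and PARM1 (5.03 ± 0.26) were higher. KCNK3, a potassium channel, had 1852 counts over the parental group against 2 in clone A (ratio 899, 95% counting interval 249 to 7430). For clone B against parental in normoxia 3697 genes were called, 1839 higher and 1858 lower, and 5710 with only the libraries compared. TRBC2 (7.60 ± 0.27), EPHB6 (7.13 ± 0.31), an ephrin receptor, and TRPV6 (6.58 ± 0.46), a calcium channel, were higher in clone B. These 3 genes lie close together on chromosome 7 (142801041 to 142885762 on GRCh38), so they need not be separate changes. MAF had 794 counts against 3 (ratio 243, 95% counting interval 82.9 to 1180). HDGFL3 was lower in clone A (−8.00 ± 0.28) and had 3 counts in clone B against 1943 (ratio 705, 95% counting interval 241 to 3420).

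Both clones against parental in normoxia shared 2200 genes with the same sign, 984 higher and 1216 lower, and 133 with opposite signs. From the separate counts 291 and 293 would be shared. SEL1L3 (4.55 in clone A and 6.34 in clone B) and TNIK (3.57 and 3.83), a kinase, were higher in both. ABCG2 (−6.87 and −5.85), a drug efflux pump, ADORA1 (−6.00 and −5.69), an adenosine receptor, and COL26A1 (−5.94 and −5.52) were lower in both. The covariance across genes was 0.587 and the correlation 0.655, against 0.045 and 0.49 in simulations with shared controls and no genotype difference. These called 0 genes, which the lack of a difference makes likely in any case. The simulations already hold the shared parental libraries, at a common spread of 14.1% against 9.83% in the real ones. Spread between those libraries is thus argued against as the source of a covariance that large. The 3 parental libraries were too few to give each clone at least 2 of its own, so shared controls may still add to the number of genes shared. With only the libraries compared, both clones against parental in normoxia gave 3835 genes.

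Interferon-stimulated genes were lower in normoxia in 14 of 19 in clone A and higher in 1, or 2 adjusted over the list alone (median −1.69, adjusted p = 5.2e-10), with OASL at −5.01 and OAS2 at −4.52. In clone B 9 were lower (median −0.61, adjusted p = 0.000175). Epithelial and classical markers were lower in 11 of 21 and higher in 2 in clone A (median −1.18, adjusted p = 3.37e-08), and lower in 9 in clone B (median −0.42, adjusted p = 1.87e-07). MHC class I genes were lower in 11 of 14 in clone A (median −0.83, adjusted p = 2.36e-07), with HLA-B at −1.78 and NLRC5, a transactivator of these genes, at −2.76. The ATF4 list was higher in 26 of 33 in clone A, or 27 adjusted over the list alone (median 1.03, adjusted p = 1.71e-22), with PHGDH, a serine synthesis enzyme, at 2.97. Collagens and matrix were lower in 13 of 24 and higher in 2 in clone A (median −1.14, adjusted p = 3.37e-08), with LAMA3 at −5.86 and SPARC at −3.46. These 7 calls held with an estimated correlation. In clone B MHC class I genes were lower in 9, or 10 adjusted over the list alone (median −0.73, adjusted p = 0.000291, but adjusted p = 0.125 with an estimated correlation). Collagens were lower in 11 and higher in 4 in clone B (median −0.52, adjusted p = 0.00608, but adjusted p = 0.398 with an estimated correlation). The ATF4 list was higher in 22 in clone B, or 25 adjusted over the list alone, and lower in 2 (median 0.61, adjusted p = 1.21e-05, but adjusted p = 0.304 with an estimated correlation).

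HIF pathway components were called lower in both clones in normoxia with medians near 0. In clone A 3 of 9 were higher and 4 lower, with a median of 0.08 and a mean of −1.25 (adjusted p = 0.000552). In clone B 2 were higher and 2 lower, or 3 lower adjusted over the list alone, with a median of −0.07 and a mean of −0.94 (adjusted p = 0.00098). ARNT2, a paralog of ARNT, stood at 20.2 CPM in parental cells, 0.246 in clone A and 1.10 in clone B. HIF targets were lower in 17 of 38 and higher in 6 in clone A, or 18 and 7 adjusted over the list alone (median −0.26, adjusted p = 0.00854). These 3 calls held with an estimated correlation. HIF targets were not called in clone B, with 10 lower and 9 higher, or 11 and 10 adjusted over the list alone (median −0.03, adjusted p = 0.677). Ribosomal proteins were higher in 31 of 44 in clone A, or 37 adjusted over the list alone (median 0.45, adjusted p = 3.1e-05, but adjusted p = 0.872 with an estimated correlation).

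In hypoxia the clones stood below parental cells for the hypoxia-induced genes. VEGFA was lower by −1.88 ± 0.14 in clone A and −2.63 ± 0.14 in clone B, SLC2A1 by −2.79 ± 0.16 and −2.37 ± 0.16, PDK1 by −2.50 ± 0.17 and −2.21 ± 0.17, and NDRG1 by −3.63 ± 0.18 and −2.95 ± 0.18. ADM was lower by −1.23 ± 0.14 and −0.59 ± 0.14. HIF1A stood at 123 ± 5.81 CPM in parental cells, 214 ± 18.9 in clone A (0.79 ± 0.16) and 334.5 ± 20.1 in clone B (1.44 ± 0.16). ASNS was higher in clone A (0.75 ± 0.13) and did not pass in clone B (−0.26, adjusted p = 0.104). UPK1B, a urothelial membrane protein, had 2078 counts in the parental group and 1 in clone A (ratio 1740, 95% counting interval 312 to 68700). TRPV6 had 833 counts in clone B against 0 in parental cells, at least 308-fold higher.

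In hypoxia 5770 genes were called in clone A, 2859 higher and 2911 lower, and 5006 in clone B, 2355 higher and 2651 lower. Both clones shared 3211 with the same sign, 1386 higher and 1825 lower, and 159 with opposite signs, against 483 and 553 expected from the separate counts. SLC7A2, a cationic amino acid transporter, was higher in both (3.63 and 5.30), and EGLN3 lower (−6.50 and −6.01). The covariance was 0.685 and the correlation 0.704, against 0.0386 and 0.477 in simulations with shared controls and no genotype difference. These called 0 genes, which the lack of a difference makes likely in any case. They already hold the shared parental libraries, at a common spread of 14.1% against 5.01% in the real ones. Spread between those libraries is thus argued against as the source of a covariance that large. The 3 parental libraries were too few to give each clone at least 2 of its own, so shared controls may still add to the number of genes shared.

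HIF targets in hypoxia were lower in 36 of 38 and higher in 1 in clone A (median −1.62, adjusted p = 1.92e-43), and lower in 34 in clone B (median −1.41, adjusted p = 9.62e-41). Glycolysis was lower in 19 of 21 in each clone (medians −1.35 and −1.33, adjusted p = 3.47e-18 and 3.22e-21). AHR targets were lower in 5 of 9 and higher in 1 in clone A (median −0.94, adjusted p = 0.00123), and lower in 7 and higher in 1, or 2 adjusted over the list alone, in clone B (median −1.41, adjusted p = 4.52e-06). MHC class I genes were lower in 13 of 14 in clone A (median −1.20, adjusted p = 2.44e-09) and 12 in clone B (median −0.88, adjusted p = 4.52e-06). Interferon-stimulated genes were lower in 15 of 19 and higher in 1 in clone A (adjusted p = 5.96e-08), and lower in 8 in clone B (adjusted p = 0.00156). HIF pathway components (medians −0.06 and −0.14, means −1.48 and −1.10, adjusted p = 2.39e-05 and 0.000186) and epithelial markers (medians −0.64 and −0.68, adjusted p = 8.95e-05 and 0.000186) were also called lower. Epithelial markers were lower in 11 of 21 in each clone, with 3 higher in clone A and 2 in clone B. Of the HIF pathway components 4 of 9 were lower and 3 higher in clone A, or 4 and 4 adjusted over the list alone, and 3 lower and 1 higher in clone B. All of these 14 calls held with an estimated correlation. Mitosis genes were higher in 20 of 23 in clone A (median 1.05, adjusted p = 7.18e-08, but adjusted p = 0.163 with an estimated correlation) and did not pass in clone B (adjusted p = 0.0903).

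In hypoxia with TIFM the clones kept lower levels of most HIF-responsive genes, but not of ADM. VEGFA was lower by −1.69 in clone A and −2.16 in clone B, SLC2A1 by −2.14 and −3.10, NDRG1 by −3.67 and −3.99, and EGLN3 by −8.04 ± 0.25 and −6.90. ADM stood at 647 ± 146 CPM in parental cells, 789 ± 90.3 in clone A and 624 ± 122 in clone B (n = 3) and did not pass in either clone (0.29 ± 0.14, adjusted p = 0.0702, and −0.05, adjusted p = 0.783). ASNS was higher in clone A (1.12) and did not pass in clone B (0.21, adjusted p = 0.163). IL11, a cytokine, was higher in both clones (4.72 ± 0.25 and 4.40), as was GLIS1 (3.76 and 5.01). GRIN2A, an NMDA receptor subunit (−6.71 and −6.27), and IGFBP3 (−5.58 and −5.32) were lower in both.

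For clone A against parental in hypoxia with TIFM 8597 genes were called, 4313 higher and 4284 lower, and 5402 with only the libraries compared. In clone B 6616 were called, 3075 higher and 3541 lower. Both clones against parental in hypoxia with TIFM shared 4301 with the same sign, 1945 higher and 2356 lower, and 405 with opposite signs, against 951 and 1090 expected from the separate counts. With only the libraries compared they shared 2503. UPK1B had 1586 counts in the parental group, against 0 in clone A, at least 443-fold lower, and 3 in clone B (ratio 527, 95% counting interval 180 to 2560). ARNT was lower in clone B (−0.39 ± 0.09, adjusted p = 0.000627) and in clone A (−0.21 ± 0.09, adjusted p = 0.0407), the latter lost without 4 of 6 libraries and with RLE factors. APOB, with 504 counts against 3 in clone B (ratio 167, 95% counting interval 56.9 to 814), is among the liver transcripts of the parental TIFM libraries. Parental TIFM replicate 3 alone held 405 of the 504. The covariance was 0.85 and the correlation 0.67, against 0.0443 and 0.489 in simulations with shared controls and no genotype difference. These called 0 genes, which the lack of a difference makes likely in any case. The real parental TIFM libraries spread more (17.3%) than the simulated ones (14.1% in common). Part of the excess may thus come from the 3 shared parental libraries, too few to give each clone at least 2 of its own.

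HIF targets in TIFM were lower in 31 of 38 and higher in 2 in clone A (median −1.51, adjusted p = 7.38e-20). In clone B 31 were lower, or 32 adjusted over the list alone, and 1 higher (median −1.58, adjusted p = 1.24e-32). MHC class I genes were lower in 11 of 14 and higher in 1 in clone A (median −1.65, adjusted p = 2.73e-07), and lower in 13 in clone B (median −1.47, adjusted p = 1.29e-09). B2M, the light chain of MHC class I, stood at 688 CPM in parental cells, 223 in clone A and 276 in clone B. Interferon-stimulated genes were lower in 12 of 19 in clone A (adjusted p = 1.28e-06) and in 13 in clone B, with 1 higher adjusted over the list alone (adjusted p = 9.16e-05). Collagens were lower in 15 of 24 in each clone, with 1 and 2 higher (medians −1.10 and −1.05, adjusted p = 4.33e-08 and 4.14e-08). Epithelial markers were lower in 14 of 21 and higher in 1 in clone A (adjusted p = 4.19e-06), and lower in 13 in clone B (adjusted p = 6.83e-08). These 10 calls held with an estimated correlation. Glycolysis was lower in 19 of 21 in clone B (median −1.44, adjusted p = 3.04e-19), which held, and lower in 13 and higher in 2 in clone A, or 13 and 3 adjusted over the list alone (adjusted p = 9.81e-06, but adjusted p = 0.171 with an estimated correlation). Cholesterol synthesis was higher in 18 of 22 and lower in 1 in clone A (median 0.69, adjusted p = 9.81e-06, but adjusted p = 0.0712 with an estimated correlation).

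Genes lower in both clones lay partly in long runs of neighbours. Of 337 windows of 40 or more consecutive tested genes, 16 had a median at or below −0.4 in both clones in normoxia, and 0 lay as far above in both. Of the 16 windows, 11 were that low in all 3 conditions. Of all 16 windows low in normoxia, 10 lay on chromosome 15, 3 on chromosome 2 between 120013005 and 170084131, and 3 on chromosome 16 between 46407 and 10818794. HDGFL3, ARNT2 and B2M lie on chromosome 15. Outside the windows the median of the MHC class I list in normoxia was −0.785 in clone A and −0.662 in clone B over 13 members, and that of the interferon list −1.656 and −0.577 over 18 members.

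**Figure D3:**
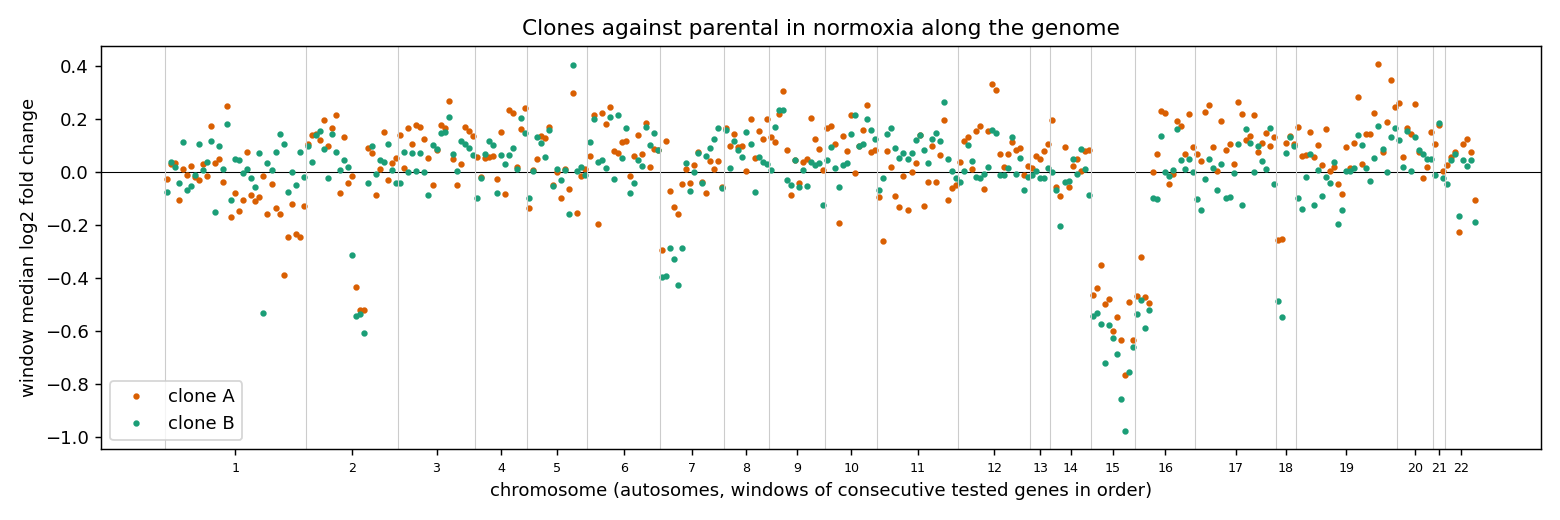
Median log2 fold change (y axis) of each window of consecutive tested genes along the autosomes (x axis, in chromosome order) for clone A and clone B against parental cells in normoxia. Points of both clones lie at or below −0.4 in runs on chromosomes 2, 15 and 16. Windows on chromosome X are not drawn.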

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

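The tests of differences in this part were planned, while the tests for opposite directions and the genes searched were chosen after the results were seen. A gene was taken when its response was called in parental cells and in both clones with opposite directions, and both differences were called. Of 13943 tested genes this held for 11 with hypoxia and 46 with TIFM. The genes below are 3 and 1 of 148 that were always named or ranked by size, partly on these same differences, so they show no rate. Genes named as list members were not searched. HIF1A fell with hypoxia in parental cells, from 197 to 123 CPM, and rose in clone A, from 136 to 214 CPM, and in clone B, from 196.5 to 334.5 CPM (n = 3 per group). The difference in its log2 response was 1.326 ± 0.225 in clone A (SE, adjusted p = 0.00039) and 1.442 ± 0.225 in clone B (adjusted p = 0.000159). GRIN2A, an NMDA receptor subunit, rose with hypoxia in parental cells, from 33.3 ± 5.71 to 52.5 ± 3.53 CPM, and fell in clone A, from 3.52 to 2.07 CPM, and in clone B, from 1.69 to 0.944 CPM (adjusted p = 0.0407). Its difference was −1.42 ± 0.286 (adjusted p = 0.00241) and −1.492 ± 0.314 (adjusted p = 0.00421).

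SLC16A14, a monocarboxylate transporter family member, fell with hypoxia in parental cells, from 9.16 ± 0.861 to 6.04 ± 0.277 CPM, and rose in clone A, from 11.3 to 17.8 CPM, and in clone B, from 16.2 to 25.3 CPM. The difference was 1.262 ± 0.173 in clone A (adjusted p = 2.54e-05) and 1.238 ± 0.172 in clone B (adjusted p = 3.14e-05). RASSF4, a RAS association domain family member, rose with TIFM in parental cells, from 10.9 ± 1.21 to 21.9 ± 1.41 CPM. It fell in clone A, from 7.27 to 2.31 ± 0.705 CPM, and in clone B, from 9.77 to 2.86 ± 0.224 CPM. The difference was −2.666 ± 0.213 (adjusted p = 1.67e-09) and −2.786 ± 0.208 (adjusted p = 8.18e-09). RASSF4 shares 7.33% of its exon length with DEPP1. Groups of 3 libraries were not tested for outliers.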

How the results depend on the processing

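The GC correction was the 1 setting in this part chosen after the results were seen, alone and together with the block. No called named gene changed direction with DESeq2, RLE factors or the block. No list call did so with an estimated correlation, fry, the block or RLE factors. For the other settings, apart from leaving out libraries, only counts of genes were compared. RLE factors, no filter, the stricter filter and the block kept each of the 22 counts of genes within 1.5 times the value in the report, and the cause of the larger moves below was not tested.

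With only the libraries of the groups compared, the counts were 6804 for hypoxia in parental, 4860 for hypoxia in clone A and 4242 for hypoxia in clone B, against 4212, 3097 and 1297 with all 27 libraries in the fit. They were 5402 for clone A against parental in hypoxia with TIFM (8597 in the report) and 5710 for clone B against parental in normoxia (3697). The hypoxia response of clone A minus parental had 2656 (869), the hypoxia response of clone B minus parental 2592 (660), and the TIFM response of clone A minus parental 3539 (5426). The hypoxia response of clone B minus clone A had 57 (0). In both clones the counts were 3835 for both clones against parental in normoxia (2200) and 2503 for both clones against parental in hypoxia with TIFM (4301). They were 1578 for the hypoxia response of both clones minus parental (438) and 370 for the TIFM response of both clones minus parental (880). Each of these counts without TIFM was higher in the narrower fit, and each with TIFM was lower. The fit with all 27 libraries gave them a shared spread (14.1%). Estimated by condition, the spread was 7.03% in normoxia, 9.6% in hypoxia and 22% in hypoxia with TIFM.

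With the GC correction the count was 2246 for hypoxia in clone B, 1505 for the hypoxia response of clone A minus parental, 1109 for the hypoxia response of clone B minus parental, 764 for the hypoxia response of both clones minus parental and 1368 for the TIFM response of both clones minus parental. The hypoxia response of clone B minus clone A had 1 gene with the GC correction and 36 with the DESeq2 Wald test. Of the 177 list calls with the preset correlation, 64 held with an estimated one, and fry made 351 calls of lists with members moving in either direction. In its directional form fry lost 16 of the 177 calls, among them calls in the hypoxia response of clone B minus clone A. The block lost 2 list calls, HIF targets for TIFM in clone A and MHC class I for the hypoxia response of clone B minus parental. RLE factors lost 2 calls, the ATF4 list for clone A against parental in hypoxia and ARNT for clone A against parental in hypoxia with TIFM. DESeq2 lost 3 single-gene calls, DCN for hypoxia in parental, and ADORA1 and FOLH1 for the TIFM response of clone A minus parental.

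Leaving out 1 library at a time gave 1916 (without clone A hypoxia replicate 1) to 2696 genes for hypoxia in clone A, 527 (without clone B hypoxia replicate 3) to 874 for hypoxia in clone B, and 933 (without parental hypoxia replicate 1) to 1456 for the TIFM response of clone B minus parental. It gave 0 to 1 for the hypoxia response of clone B minus clone A, the 1 without clone B hypoxia replicate 3, and 288 (without parental hypoxia replicate 1) to 515 for the hypoxia response of both clones minus parental. Of 442 called pairs of a named gene and a comparison, 34 lost the call without at least 1 library and 0 turned. Of the 177 list calls, 31 lost the call and 0 turned.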

Other observations

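The tests of liver transcripts in single libraries and of runs of neighbouring genes as copy number were chosen after the results were seen, as was the GC correction, and the other tests in this part before. CCL2, a chemokine, stood at 215 CPM in parental normoxia, 1.03 in clone A and 8.09 in clone B (n = 3 per group). In hypoxia CCL2 stood at 519, 6.40 and 56.8 CPM, and in hypoxia with TIFM at 148, 1.07 and 15.5 CPM, in the same order. EGLN3 stood at 9.94 CPM in parental normoxia, 41.7 in hypoxia and 68.6 with TIFM, and stayed at or under 0.641 CPM in each group of both clones. TXNIP stood at 12, 7.1 and 28.7 CPM in normoxia in parental cells, clone A and clone B. It stood at 6.05, 3.94 and 5.17 CPM in hypoxia and at 109, 229 and 78.2 CPM with TIFM. Across genes the log2 response to hypoxia correlated at 0.484 between parental cells and clone A, 0.502 between parental cells and clone B, and 0.604 between the clones.

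Transcripts of liver genes, 9 genes summed, stood out in 6 libraries. These were clone B hypoxia replicate 3 (13 CPM), parental TIFM replicates 1 to 3 (12.5, 8.04 and 35.9 CPM) and clone A TIFM replicates 1 and 2 (33.5 and 32.7 CPM), against 0.379 CPM or less elsewhere. Expression induced by TIFM is argued against for clone B hypoxia replicate 3, which was grown without TIFM. In the TIFM libraries it stays open. The lowest library there stood at 0.458% of its group's highest, but that is 1 library, clone A TIFM replicate 3, and most of the summed genes were chosen partly for their low counts in it. Liver-type RNA or reads entering single libraries may be a source, with 2 groups holding libraries both with and without the transcripts, and cannot be told apart from other sources because the labels give no batch. ALB, albumin, had 904 counts in the 6 libraries, while APOA1, APOH and TTR together had 146, or 16.2% of that.

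Runs of neighbouring genes were lower in both clones. A difference in gene copy number between the clones and parental cells may account for them, as 16 of 337 windows had a median at or below −0.4 in both clones against a highest of 0 in 100 shuffles of gene positions. Such runs as the source of most genes lower in both clones are argued against, since 26.2% of these genes (318 of 1216) lay in the windows, which hold 4.65% of tested genes. Of genes with a smaller hypoxia response in both clones 3.47% lay there. In 1 clone alone, 2 windows in clone A, both on chromosome X (medians −1.089 and −1.121), and 6 in clone B, on chromosomes 1, 7, 15, 16 and 18, lay at or below −0.4, against highest counts of 1 and 0 in the shuffles. Copy number was not measured, and a shared parent cell of the clones stays open and untested.

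The TIFM response differed from the parental one for more genes in clone A than in clone B. GC-related differences between libraries as the whole cause are argued against, since with the GC correction clone A kept a count of 6019 against 2071 in clone B. Before correction, the Spearman correlation across genes between this TIFM difference and transcript GC was 0.24 for clone A and −0.3 for clone B. A single clone A TIFM library as the cause is argued against too, since the lowest count without 1 of them was 4881, against 1450 for clone B. The clone A TIFM libraries had a biological coefficient of variation of 29.2%, against 17.3% in clone B with TIFM and 14.1% in the fit of all libraries. A spread above that of the fit can raise the number of calls, and neither test above addresses it. With only the libraries compared the clone A count was lower. Ribosomal protein shares in the clone A TIFM libraries were 4.96%, 5.88% and 7.77%. A property of clone A itself may remain beside the wider spread, and 1 clone cannot separate it from the handling of that group.

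Other splits of the same libraries were counted for each result. For 12 comparisons of 3 libraries with 3, the real split gave the highest count in 1 of 10 splits, and with so few splits the share cannot be under 0.05. For hypoxia the real counts were 4212 in parental cells, 3097 in clone A and 1297 in clone B, each against a highest other of 0. For TIFM they were 5881 against 0 in parental cells, 9368 against 932 in clone A and 7490 against 0 in clone B. For clone A against parental cells they were 4408 against 0 in normoxia, 5770 against 0 in hypoxia and 8597 against 4553 with TIFM. For clone B they were 3697 against 0, 5006 against 0 and 6616 against 60.

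With 21 splits, only the real grouping reached its own count, a share under 0.05, for 6 results. These were both clones against parental in normoxia (2200, highest other 1468), in hypoxia (3211, 1880) and in hypoxia with TIFM (4301, 3943), the hypoxia response of both clones minus parental (438, 227), the hypoxia response of clone B minus parental (660, 0) and the TIFM response of clone A minus parental (5426, 4791). Splits other than the real one were as large for the TIFM response of both clones minus parental (2 of 21 splits as large, 880, highest other 1301), the hypoxia response of clone A minus parental (3 of 21, 869, highest other 3694) and the TIFM response of clone B minus parental (7 of 21, 1450, highest other 4544). In the last 2 the highest other split called several times the real count. All of these splits shuffled libraries of different genotypes separately in each condition, so differences between genotypes enter their counts. They therefore cannot decide whether chance gave any of these results. A real count of 0 for the hypoxia response of clone B minus clone A made each of the 21 splits as large by construction (highest other 0), so the splits say nothing about it.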
